A study of Mus musculus with 12 samples.

How the data were processed

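Bulk RNA sequencing of whole liver was analysed from 12 mice: 3 given carbon tetrachloride alone (control) and 3 each given carbon tetrachloride with curcumin at 25 mg/kg (low), 50 mg/kg (medium) or 100 mg/kg (high). Groups, doses and replicate numbers were taken from the labels. The labels' protocols name TRIzol extraction of total RNA and a Hieff library kit, state that mice were housed 3 to a cage, and do not say whether the control mice were given a gavage without curcumin. With 3 mice in a group and 3 in a cage, cage and group may coincide.

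The authors deposited 1 table of gene counts, whole numbers that were not normalized, with 1 column per library and Ensembl gene IDs as rows. Per the submitters' processing notes, the tools were fastp 0.23.4, STAR 2.7.10b and StringTie 2.2.1 on the mm39 genome build. Which step made the counts, and how it treated strand and reads that fit several genes, is not given in the sources used here. All 12 columns matched a label, and 0 columns were left over. Of 56923 IDs, 52073 (91.5%) had a symbol in GENCODE M21, and IDs without one held 0.812% of all counts. Since that annotation is for another build, it was used for names, sequence identity and transcript length, and no coordinates are given.

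Library totals ran from 36015134 to 70376474 counts, where 3 counts correspond to 0.0426 to 0.0833 CPM. Transcripts of nuclear genes were compared with the mitochondrial ones by BLAST+ 2.17.0. A gene was taken as a nuclear copy at an identity of at least 95% over at least 80% of its length, which gave 11 genes. Some of these had counts close to those of their mitochondrial counterpart (Gm28437 had 1.001 times the counts of mt-Co3), so the same reads may have been counted for both, and none of these genes or their counterparts is interpreted singly. Libraries of the same group differed far beyond sampling noise, with a chi-square per degree of freedom of 46.6 or more for every pair, so that no library was a second copy of another. The female-specific transcript Xist was present in all 12 libraries and the Y-linked Ddx3y was at or near 0, so all fit females, a sex that the labels do not give.

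Gene tests were run in R 4.3.3 with edgeR 4.0.16: genes passing filterByExpr for the groups (16839), TMM normalization, robust dispersion and quasi-likelihood fits, and glmQLFTest with all 12 libraries in 1 fit so that the groups share an estimate of the spread. Each dose was tested against control. A slope on dose in mg/kg (printed over the range of 100) and an F test among the doses used the same settings. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Standard errors were derived from the fold change and its F statistic.

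The 51 gene lists (pathways, cell type markers and signs of handling and RNA quality) were written before the data were examined, as were the tests and the alternatives listed below, except the last ones. Of these lists 48 had at least 5 tested genes. The pancreas, adipose and skeletal muscle lists had 1, 2 and 3 tested genes and gave no test. Lists were tested with camera (limma 3.58.1) on voom values with the preset inter-gene correlation of 0.01, and again with the correlation estimated from the data. The second form is the stricter one, because genes of a list vary together between mice. fry, which asks whether a list changed at all and not whether it changed more than other genes, was run as a further form. A list score is the mean over genes of log2 CPM (prior count 2, after a first run with a smaller prior count that led to the same readings) centred per gene, and was compared between groups by exact two-sided permutation. With 3 libraries against 3 the smallest possible p is 0.1. The slope of the mitochondrial share on dose was tested by permutation. The 48 correlations of list scores with the mitochondrial share were adjusted together.

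Named genes follow a rule written beforehand. In each comparison it takes the 10 genes per direction with the largest change among those past the threshold with no overlap between groups. Where fewer than 5 pass, as in every comparison here, it takes the 5 per direction with the smallest p, with a mean log2 CPM of at least 1 and a symbol that is neither a predicted locus nor an immunoglobulin or T cell receptor segment. It adds Slamf8, Tnf, Nfkb1, Rela and Nfkbia, and up to 4 members of a list with the smallest p. Genes so named are therefore reported with their values and not as changed.

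The gene test was tested on simulated counts for the 16839 genes with the real means, library sizes and dispersions and 200 genes with a mean log2 CPM of at least 1 changed in 1 dose group. For the low group it recovered 4% of 2-fold, 80% of 4-fold and 98% of 8-fold changes, with 2 false calls. For the medium group these were 6%, 74% and 94% with 7 false calls, and for the high group 8%, 66% and 98% with 4 false calls. Simulated genes varied independently of each other, unlike those of the real libraries, so these rates may not hold for the real data. A count of 0 in the real data therefore does not mean that large changes are absent. In the simulated data camera found a list of 20 genes lowered 2-fold for each dose, and 1 to 2 of 100 random lists had p under 0.05. Because the simulated genes were independent, this does not check the preset form for lists whose genes vary together.

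Alternatives were DESeq2 size factors in place of TMM, DESeq2 1.42.0 in place of edgeR, no filter on low counts or a CPM of at least 1 in 3 libraries, fits with only the groups compared, the replicate number as a block, limma voom with library weights, a log2 fold change of at least 1 as well, other dose scales, and each library left out. After the data were seen, 2 further alternatives were added: the mitochondrial share as a covariate, and mitochondrial genes with their copies left out. A fit without the 4 libraries under 50% mitochondrial counts was also run. It gave a few gene calls in most comparisons and turned the direction of lists that follow the share, and it is not reported because it picks libraries by a value measured in them.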

Results

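Liver RNA was sequenced from 12 wild-type C57BL/6J mice in 4 groups of 3, which the labels give as biological replicates. All mice were 6 weeks old at the start and had carbon tetrachloride, a hepatotoxin whose repeated use scars the liver, injected 2 times a week for 6 weeks (200 µL of a 7.5% solution in olive oil). The control group had this injury alone. The other groups were also given curcumin, the yellow polyphenol of turmeric, by daily gavage over 2 weeks at 25 mg/kg (low), 50 mg/kg (medium) or 100 mg/kg (high). Every comparison is therefore between injured livers, and no liver without carbon tetrachloride was analysed here. The libraries held 36015134 to 70376474 counts, and 17197 to 21402 genes had at least 1 count in a library.

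Mitochondrially encoded transcripts took a large and uneven part of the counts. Their share ran from 30.3% in high replicate 1 to 64.7% in high replicate 2, with 95% Wilson intervals of at most ± 0.0161 percentage points that cover counting error only. Group means were 61.2% ± 2.81 in control, 56.9% ± 12.1 in low, 54.7% ± 6.01 in medium and 45.7% ± 17.5 in high (SD, n = 3 each). A test of 3 libraries against 3 cannot decide here (exact permutation p = 0.8, 0.2 and 0.4, where 0.1 is the smallest possible). The slope of the share on dose was -15.3 ± 7.79 percentage points over 100 mg/kg (permutation p = 0.0751, 95% interval -32.6 to 2.08; Spearman rho = -0.389, permutation p = 0.221), which leaves a trend with dose open. High replicates 1 and 3, at 30.3% and 42.1%, pull this slope down, while high replicate 2 lay at 64.7%. The slope was not refitted with single libraries left out. Another 10.9% to 23.3% of the counts fell on 11 nuclear genes of near-identical sequence, 5 of which had counts close to those of their mitochondrial counterpart. The transcript of albumin (Alb), the main plasma protein made by hepatocytes, took 1.35% to 10.1% of the counts outside mitochondrial genes and these copies, and was highest in the 4 libraries with the lowest mitochondrial share. The first principal component of the 12 libraries held 29.4% of the variance and followed the mitochondrial share (Pearson r = -0.988, permutation p = 2e-05; Spearman rho = -0.958, permutation p = 1e-05, the smallest that the permutations can give). Without the 2 libraries farthest from the median, r was -0.969. Across libraries the hepatocyte list (r = -0.981, adjusted p = 0.00024 by permutation), the oxidative phosphorylation list (r = -0.964, adjusted p = 0.00096 by permutation) and the ribosomal protein list (r = -0.818, adjusted p = 0.00364 by permutation) moved against this share, among 22 of the 48 lists tested. The mitochondrially encoded list itself and the circadian clock list (r = 0.728, adjusted p = 0.0152 by permutation) moved with it, the latter without passing by Spearman's rho (0.643, adjusted p = 0.0649 by permutation) and with r = 0.445 without the same 2 libraries. By Spearman's rho the first 2 held (-0.951 and -0.902, adjusted p = 0.00048 and 0.00108 by permutation), while the ribosomal protein list did not pass (-0.643, adjusted p = 0.0649 by permutation). The immediate early list (r = -0.0974, permutation p = 0.767) and the TNF and NF-κB list (r = 0.307, permutation p = 0.329) gave no such relation.

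**Figure D1:**
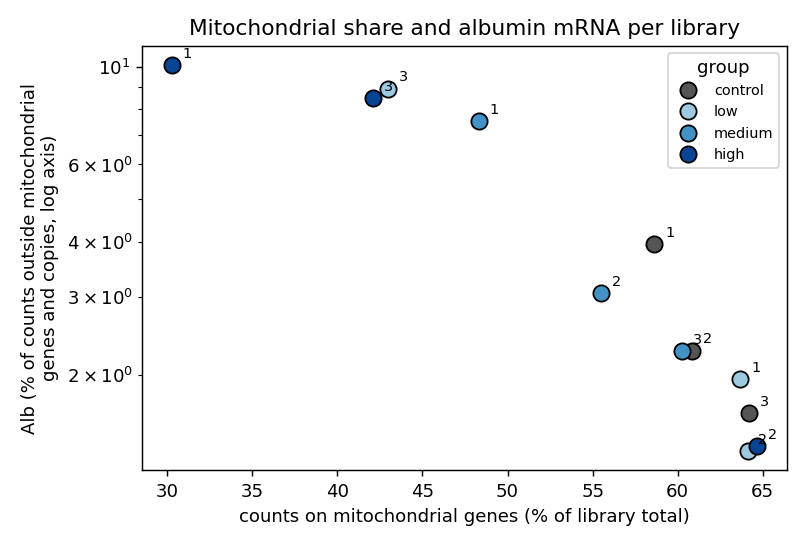
Each point is 1 library, with counts on mitochondrial genes as a percentage of the library total on the x axis and Alb as a percentage of the counts outside mitochondrial genes and their nuclear copies on a log y axis; numbers are replicates and colours are groups. The library with the lowest mitochondrial share, high replicate 1 at 30.3%, has the highest Alb value, 10.1%.

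The low dose was compared with the control to ask which liver transcripts differ at 25 mg/kg. Immediate early genes, which cells switch on within minutes of a stimulus, were lower as a set. Of 20 measured members 18 lay below the control, with a median log2 fold change of -1.02 (camera adjusted p = 4.16e-13; adjusted p = 0.0647 with an estimated correlation). In this list Fos had a log2 fold change of -3.17 ± 0.62 (SE, n = 3 against 3), Egr1 -2.24 ± 0.42 and Jun -1.87 ± 0.44. For each of them all 3 low-dose libraries lay below all 3 controls, and Jun was at -1.20 without control replicate 3. Of the TNF and NF-κB genes, 35 of 39 lay lower with a median of -0.58 (adjusted p = 2.46e-10; adjusted p = 0.107 with an estimated correlation). Among them Tnfaip2, a gene induced by TNF, was at -1.84 ± 0.31, Junb at -1.57 ± 0.37 and Relb, an NF-κB subunit, at -1.16 ± 0.29. Interferon response genes lay lower in 30 of 31 members with a median of -0.58 (adjusted p = 6.59e-12; adjusted p = 0.107 with an estimated correlation), including the antiviral GTPase gene Mx1 at -1.67 ± 0.44.

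Several immune cell lists were lower at the low dose too, in part because control replicate 2 stands apart in them. Its neutrophil score was 1.78 against 0.23 and 0.202 in the other controls, and its Kupffer cell score 0.954 against 0.279 and -0.173. Without it S100a9 was at -0.59, Tlr2 at -0.96 and Timd4 at -1.23, and the score differences of the neutrophil and Kupffer cell lists went from -1.39 to -0.87 and from -0.613 to -0.313. All 18 B and plasma cell markers lay below the control, with a median of -1.01 (adjusted p = 1.84e-10; adjusted p = 0.107 with an estimated correlation). Kupffer cells, the resident macrophages of the liver, had 14 of 16 markers lower, with a median of -0.52 (adjusted p = 0.00018; adjusted p = 0.305 with an estimated correlation), among them Clec4f at -1.27 ± 0.31 and Timd4 at -1.88 ± 0.49. Neutrophil markers were lower in 10 of 11 members, with a median of -1.61 (adjusted p = 0.00018; adjusted p = 0.305 with an estimated correlation) and with S100a9 at -1.28 ± 0.39. Inflammasome and Toll-like receptor genes were lower in 23 of 25 members, with a median of -0.52 (adjusted p = 5.46e-07; adjusted p = 0.107 with an estimated correlation) and with Tlr2 at -1.82 ± 0.63. In the other direction, 20 of 24 lipogenesis genes lay higher, with a median of 0.42 (adjusted p = 1.39e-05; adjusted p = 0.276 with an estimated correlation). Lpin1, a phosphatidate phosphatase, stood at 1.94 ± 0.63 through low replicate 3, and at 0.53 without it. All 76 ribosomal protein genes lay higher, with a median of 0.92 (adjusted p = 4.62e-21; adjusted p = 0.432 with an estimated correlation), and so did 63 of 64 oxidative phosphorylation genes, with a median of 0.71 (adjusted p = 9.31e-06; adjusted p = 0.807 with an estimated correlation). Both of these lists move against the mitochondrial share, which was 43.0% in low replicate 3 against 63.7% and 64.1% in the other low libraries. Without that library the oxidative phosphorylation score difference went from 0.542 to 0.059.

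No single gene passed the test at the low dose. edgeR's quasi-likelihood test called 0 of 16839 genes at an adjusted p under 0.05, with 1008 at an unadjusted p under 0.05 where chance gives 842, while DESeq2 called 32 (8 higher and 24 lower) and limma voom with library weights 0. Without low replicate 3 the edgeR count was 2. The smallest p-values among well-expressed named genes belonged to Dvl2 (1.01 ± 0.23), Tcim (1.89 ± 0.44), Lsm3 (0.89 ± 0.21), Pfkfb3 (1.53 ± 0.37) and Mfsd2a (2.04 ± 0.50) on the higher side, each with adjusted p = 0.764. On the lower side they belonged to Tnfaip2 (adjusted p = 0.472), Egr1 (adjusted p = 0.71), Fgd2 (-1.55 ± 0.33), Igsf6 (-1.95 ± 0.43) and Fmnl1 (-1.48 ± 0.33), the last 3 with adjusted p = 0.764. Mfsd2a was at 2.75 without control replicate 1, and Igsf6 at -1.16 without control replicate 2. Adjusted over the list alone and not over the 48 lists, 6 of 20 immediate early genes, 3 of 39 TNF and NF-κB genes, 3 of 18 B and plasma cell genes and 4 of 16 Kupffer cell genes passed, all lower. Among other lists, 5 of 11 neutrophil genes (all lower) and 5 of 20 female-biased liver genes (1 higher and 4 lower) did so too. In total 22 of 48 lists passed with the preset correlation (6 higher and 16 lower), 0 with an estimated correlation and 5 by fry. Leaving out control replicate 2 brought the 22 lists to 14. For 13.8% of genes the low and control libraries did not overlap, where chance gives 10%.

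**Figure D2:**
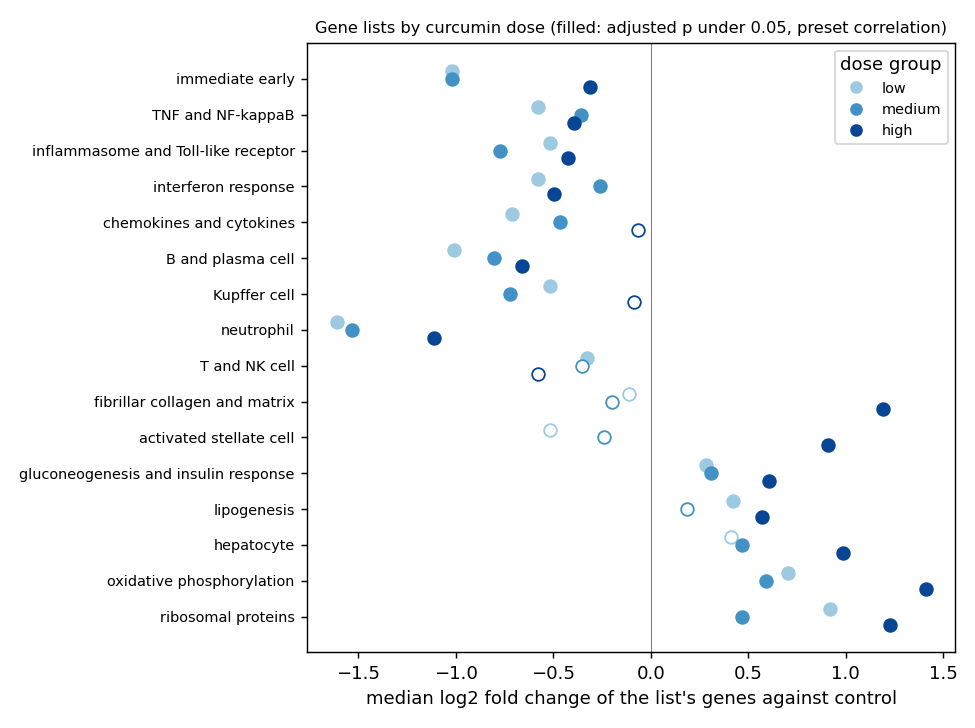
Median log2 fold change against control of the genes in 16 lists fixed beforehand (x axis), with 1 point per dose; filled points have a camera adjusted p under 0.05 with the preset correlation and open points do not. The immediate early median is -1.02 at the low and medium doses and -0.31 at the high dose, and the oxidative phosphorylation median is 0.71, 0.59 and 1.41. Scaled by library totals, the TNF and NF-κB medians turn to 0.08 at the medium and 0.11 at the high dose, since the median of all genes then shifts by 0.47 and 0.57. Scaled by totals without mitochondrial genes and copies, they are -0.462 and -0.75.

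The medium dose was set against the control for the same question at 50 mg/kg. Immediate early genes were again lower as a set, in 18 of 20 members with a median of -1.02 (adjusted p = 1.55e-17), and this was the only list of the 48 that also passed with an estimated correlation (adjusted p = 0.0239). Fos was at -3.25 ± 0.61, Egr1 at -2.44 ± 0.42, Nr4a1 at -2.05 ± 0.40, Jun at -2.03 ± 0.44 and Junb at -1.82 ± 0.37, with no overlap between the groups for any of the 5. Without control replicate 3 Jun was at -1.36. TNF and NF-κB genes lay lower in 32 of 39 members with a median of -0.36 (adjusted p = 9.11e-08; adjusted p = 0.266 with an estimated correlation). Tnfaip2 stood at -1.66 ± 0.30, the NF-κB cofactor gene Bcl3 at -1.27 ± 0.33 and the leukocyte adhesion gene Icam1 at -1.11 ± 0.32. Without control replicate 2 the score difference of this list went from -0.485 to -0.31. Scaled by library totals, which include the mitochondrial counts, the median of all genes moved by 0.47 at this dose and the median of this list to 0.08, so directions here are relative to the bulk of genes. The interferon response, SLAM family, and fibrillar collagen and matrix lists then turn too, to 0.17, 0.03 and 0.27. With totals that leave out mitochondrial genes and copies as the scale, the median of all genes moved by -0.076. The TNF and NF-κB median was then -0.462, and those of the lists just named were -0.375, -0.511 and -0.272.

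Inflammasome and Toll-like receptor genes were lower in 23 of 25 members at the medium dose, with a median of -0.77 (adjusted p = 9.11e-08; adjusted p = 0.113 with an estimated correlation). Tlr2 was at -2.10 ± 0.63 (-1.24 without control replicate 2, -3.02 without medium replicate 3) and the necroptosis kinase gene Ripk3 at -1.54 ± 0.49. Kupffer cell markers lay lower in 14 of 16 members with a median of -0.72 (adjusted p = 2.61e-06; adjusted p = 0.314 with an estimated correlation), among them Cd5l at -1.22 ± 0.33. B and plasma cell markers lay lower in 15 of 18 members with a median of -0.81 (adjusted p = 2.74e-05; adjusted p = 0.371 with an estimated correlation). Gluconeogenesis and insulin response genes lay higher in 14 of 21 members with a median of 0.31 (adjusted p = 0.033; adjusted p = 0.598 with an estimated correlation). Foxo1, a transcription factor restrained by insulin, was at 1.19 ± 0.27, the alanine transaminase gene Gpt2 at 1.16 ± 0.32, the serine dehydratase gene Sds at 1.60 ± 0.46, and Lpin1 at 2.75 ± 0.64. Control replicate 1, with a score of 0.127, lay above all 3 medium libraries in this list (exact permutation p = 0.4). Its score difference of 0.227 became 0.433, 0.0974 and 0.151 without control replicates 1, 2 and 3. Those of the Kupffer cell and B and plasma cell lists went from -0.635 to -0.335 and from -0.499 to -0.245 without control replicate 2. Fibrillar collagen and matrix genes gave no call, with 8 members higher and 16 lower (median -0.20, adjusted p = 0.345).

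At the medium dose edgeR's quasi-likelihood test also called 0 of 16839 genes, with 940 at an unadjusted p under 0.05, where DESeq2 called 80 (57 higher and 23 lower) and limma voom with library weights 35 (28 higher and 7 lower). Over all genes tested, the smallest adjusted p of this test was 0.221. On the higher side the smallest p-values among well-expressed named genes belonged to Tcim (2.69 ± 0.45), the interleukin-6 receptor gene Il6ra (1.72 ± 0.32), Fbxo31 (1.83 ± 0.35), Alas1, which encodes the first enzyme of haem synthesis (1.99 ± 0.39), and the lipid droplet gene Plin5 (2.67 ± 0.53). On the lower side they belonged to Egr1, Tnfaip2, Junb, Osgin1 (-2.18 ± 0.47, and -1.46 without control replicate 3) and Jun, and all 10 genes had adjusted p = 0.353. Adjusted over the list alone and not over the 48 lists, 8 of 20 immediate early genes, 7 of 39 TNF and NF-κB genes and 4 of 21 gluconeogenesis and insulin response genes passed. Of the 48 lists 22 passed with the preset correlation (7 higher and 15 lower), against 1 with an estimated correlation and 1 by fry, and leaving out control replicate 2 brought the 22 to 14. For 14% of genes the medium and control libraries did not overlap, where chance gives 10%.

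**Figure D3:**
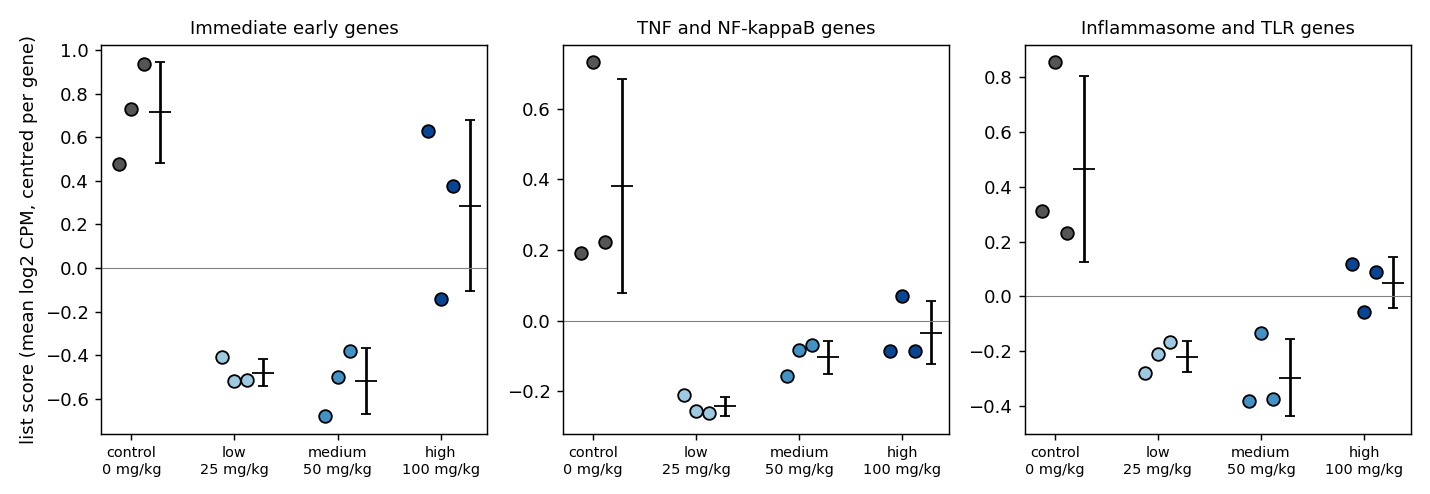
List score (mean log2 CPM of the list's genes, centred per gene) of each library by group, for the immediate early, TNF and NF-κB, and inflammasome and Toll-like receptor lists; bars give mean ± SD of 3 libraries. All 3 controls lie above all 9 curcumin libraries in the TNF and NF-κB and in the inflammasome and Toll-like receptor panel.

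The high dose was compared with the control in the same way at 100 mg/kg. TNF and NF-κB genes lay lower in 32 of 39 members with a median of -0.40 (adjusted p = 0.000291; adjusted p = 0.601 with an estimated correlation). The neutrophil chemokine gene Cxcl1 stood at -1.78 ± 0.47, Junb at -1.37 ± 0.36 and Tnfaip2 at -1.26 ± 0.30, while the TNF receptor gene Tnfrsf1b lay on the other side at 1.26 ± 0.31. Interferon response genes lay lower in 26 of 31 members with a median of -0.50 (adjusted p = 8.22e-06; adjusted p = 0.601 with an estimated correlation), with Ifi44 at -1.06 ± 0.28 and Mx1 at -1.58 ± 0.43. Scaled by library totals, where the median of all genes moved by 0.57, these 2 list medians became 0.11 and 0.01. Immediate early genes lay lower in 14 of 20 members with a median of -0.31 that turns to 0.33 under that scaling (adjusted p = 0.0256; adjusted p = 0.601 with an estimated correlation). Egr1 was at -1.04 ± 0.40. With totals that leave out mitochondrial genes and copies as the scale, the median of all genes moved by -0.287. The TNF and NF-κB, interferon response and immediate early medians were then -0.75, -0.847 and -0.524. B and plasma cell markers lay lower in 11 of 18 members with a median of -0.66 (adjusted p = 0.00645; adjusted p = 0.601 with an estimated correlation), with Ighd at -1.64 ± 0.37 and Ms4a1 at -1.80 ± 0.44. The score difference of this list, -0.405, became -0.15 without control replicate 2, -0.631 without control replicate 3 and -0.258 without high replicate 2. That of the TNF and NF-κB list went from -0.415 to -0.24 without control replicate 2, and that of the immediate early list from -0.427 to -0.212 without high replicate 2.

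Matrix genes differed from this direction at the high dose. Of 24 fibrillar collagen and matrix genes 22 lay higher, with a median of 1.19 (adjusted p = 0.000175; adjusted p = 0.601 with an estimated correlation). The proteoglycan genes Dcn and Lum were at 1.70 ± 0.47 and 1.82 ± 0.57, and Postn at 1.15 ± 0.35. Activated stellate cells, which lay down scar matrix, had 16 of 19 markers higher with a median of 0.91 (adjusted p = 0.0105; adjusted p = 0.626 with an estimated correlation), with the growth factor gene Ccn2 at 2.08 ± 0.50. Single libraries carry these lists. Without high replicates 1 and 2 in turn, the matrix score difference of 0.897 became 0.431 and 1.47, and the stellate one of 0.652 became -0.0462 and 1.49 (1.01 and 0.352 without control replicates 2 and 3). The matrix score was 1.67 and 0.95 in high replicates 1 and 3 but -0.396 in replicate 2, below 2 of the 3 controls (exact permutation p = 0.3). Markers of the mesothelium, which covers the liver surface, lay higher in 8 of 8 members too (adjusted p = 0.00792; adjusted p = 0.601 with an estimated correlation), with scores of 1.57 and 1.71 in high replicates 1 and 3. Their score difference of 1.07 became 0.512, 1.76 and 0.694 without control replicate 1, high replicate 2 and high replicate 3. High replicate 1 also held 3124 counts of the skeletal muscle gene Tnnt3, against 0 to 14 in the other libraries, so this library held transcripts of muscle as well. The matrix and activated stellate cell lists move against the mitochondrial share across libraries (r = -0.868 and -0.842, adjusted p = 0.00208 and 0.00355 by permutation). By Spearman's rho this held for the second alone (-0.657, adjusted p = 0.0596, and -0.797, adjusted p = 0.0145, by permutation). Without the 2 libraries farthest from the median share, which are high replicates 1 and 3, r was -0.605 and -0.545. With the share as a covariate, an alternative chosen after the data were seen, neither list passed (adjusted p = 0.674 and 0.417), and the second pointed lower. Gluconeogenesis and insulin response genes lay higher in 15 of 21 members with a median of 0.61 (adjusted p = 0.000605; adjusted p = 0.601 with an estimated correlation). Foxo1 was at 1.35 ± 0.27 and Lpin1 at 2.79 ± 0.65. Hepatocyte markers lay higher in 24 of 25 members (median 0.99, adjusted p = 0.000175; adjusted p = 0.601 with an estimated correlation), as did all 76 ribosomal protein genes (median 1.23, adjusted p = 5.36e-12; adjusted p = 0.601 with an estimated correlation) and all 64 oxidative phosphorylation genes (median 1.41, adjusted p = 1.97e-11; adjusted p = 0.601 with an estimated correlation), the lists that move against the mitochondrial share. Without high replicates 1 and 2 in turn, their score differences of 0.876, 0.957 and 1.08 became 0.435 and 1.4, 0.381 and 1.52, and 0.499 and 1.72. With the mitochondrial share as a covariate, the hepatocyte and oxidative phosphorylation lists did not pass and pointed lower, as given further below.

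edgeR's quasi-likelihood test called 0 of 16839 genes at the high dose, with 2152 at an unadjusted p under 0.05, where DESeq2 called 157 (78 higher and 79 lower) and limma voom with library weights 256 (84 higher and 172 lower). DESeq2 and limma voom shared 97 of these calls. limma voom gave high replicates 1, 2 and 3 weights of 0.284, 0.316 and 2.95, so its calls rest mostly on replicate 3. The unadjusted count rested on single libraries: it was 1130 without high replicate 1, 4803 without high replicate 2, 1382 without control replicate 2 and 1363 without control replicate 3. Over all genes tested, the smallest adjusted p of the edgeR test was 0.114. Among well-expressed named genes, the smallest p-values on the higher side belonged to the glycolysis regulator gene Pfkfb3 (2.23 ± 0.38), Rbm14 (1.10 ± 0.21), Tcim (2.37 ± 0.45), Foxo1 and Tmem50a (1.22 ± 0.25). Those on the lower side belonged to the kinase gene Pim1 (-1.37 ± 0.26), H2-Ob (-1.96 ± 0.39), Apobec1 (-1.22 ± 0.26), Slc35d2 (-1.04 ± 0.22) and Nab2 (-1.21 ± 0.27), and all 10 had adjusted p = 0.32. Adjusted over the list alone and not over the 48 lists, 8 of 39 TNF and NF-κB genes (7 lower), 8 of 18 B and plasma cell genes (7 lower) and 0 of 24 fibrillar collagen and matrix genes passed, the last with 9 at an unadjusted p under 0.05. Of the 48 lists 25 passed with the preset correlation (17 higher and 8 lower), against 0 with an estimated correlation and 0 by fry. For 13% of genes the high and control libraries did not overlap, where chance gives 10%.

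Slamf8, a receptor of the SLAM family found on macrophages that the title of the series names, was measured near the limit of detection. It had 0 to 54 raw counts per library, and the mean was 0.65 ± 0.30 CPM in control, 0.28 ± 0.05 in low, 0.13 ± 0.12 in medium and 0.34 ± 0.14 in high (SD, n = 3 each). The log2 fold change was -1.23 ± 0.86 at the low dose (adjusted p = 0.86), -2.32 ± 0.89 at the medium dose (adjusted p = 0.791) and -0.94 ± 0.84 at the high dose (adjusted p = 0.626). Only at the medium dose did all 3 libraries lie below all controls, and medium replicate 1 held 0 counts, where 3 counts would be 0.0465 CPM on this scale. Without medium replicate 3 the medium value was -3.06. Tnf, at 0.81 ± 0.60 CPM in control, had -1.86 ± 0.69 (adjusted p = 0.8), -2.25 ± 0.69 (adjusted p = 0.642) and -0.79 ± 0.66 (adjusted p = 0.602). Without control replicate 2 these were -1.11, -1.49 and -0.03. No difference passed for the NF-κB subunit genes Nfkb1 and Rela or the inhibitor gene Nfkbia, with Nfkb1 at -0.39 ± 0.24, -0.25 ± 0.24 and -0.40 ± 0.24, Rela at -0.09 ± 0.26, -0.29 ± 0.26 and -0.17 ± 0.26, and Nfkbia at -0.18 ± 0.22, -0.06 ± 0.22 and 0.22 ± 0.22 from low to high. Of 9 measured SLAM family genes, 8 lay lower at the low dose (adjusted p = 0.0314; adjusted p = 0.432 with an estimated correlation), 8 at the medium dose (adjusted p = 0.0252; adjusted p = 0.587 with an estimated correlation) and 7 at the high dose (adjusted p = 0.134). Control replicate 2 stands apart here too, and without it the score differences went from -0.555, -0.635 and -0.607 to -0.203, -0.282 and -0.255.

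**Figure D4:**
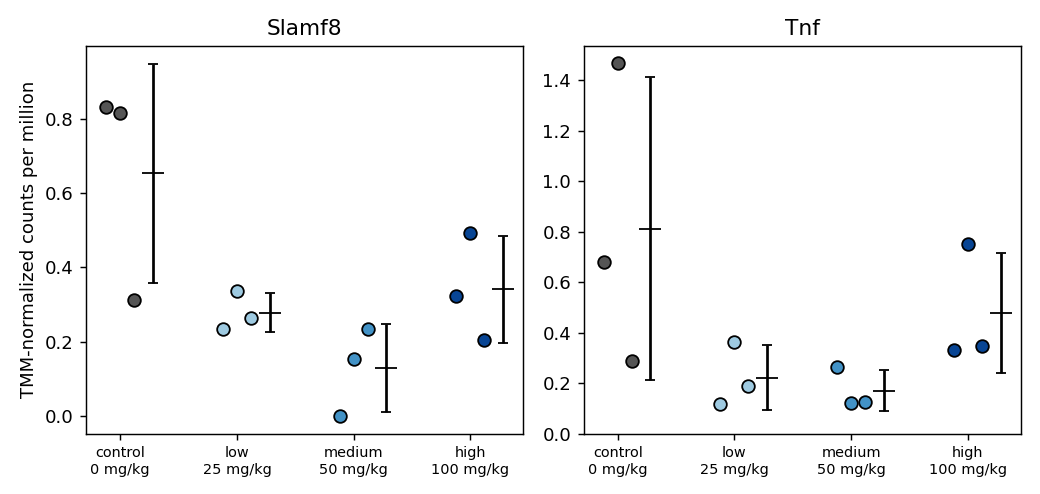
TMM-normalized CPM of Slamf8 and Tnf in each library by group, with mean ± SD of 3 libraries per group. Control means are 0.65 for Slamf8 and 0.81 for Tnf, and all 3 medium libraries lie below all controls in both panels, while libraries of the low and high groups overlap the controls.

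A slope of log2 expression on dose, with the control at 0, asked for genes that follow the dose. The clearest upward slopes over the whole range to 100 mg/kg belonged to Ddit4, a stress-induced inhibitor of mTORC1 (2.23 ± 0.41 log2 units), the transcription factor gene Cebpd (1.14 ± 0.23), Ppat, which encodes the first enzyme of purine synthesis (1.04 ± 0.22), Rasgef1b (1.47 ± 0.31) and Tmem50a (1.19 ± 0.26). Ddit4 had means of 1.64, 2.39, 4.51 and 7.54 CPM from control to high. The low mean rests largely on low replicate 3, with 392 raw counts (not scaled for depth) against 38 and 49 in low replicates 1 and 2. The clearest downward slopes belonged to Slc35d2 (-1.02 ± 0.20), H2-Ob, an MHC class II chain of B cells (-1.80 ± 0.38), the RNA-editing enzyme gene Apobec1 (-1.14 ± 0.24), Pheta1 (-1.34 ± 0.28) and Abcb6 (-1.36 ± 0.30). None of these passed (adjusted p = 0.291 for each but Abcb6, at 0.324). edgeR's quasi-likelihood test called 0 genes for the slope, with 1853 at an unadjusted p under 0.05, and DESeq2 called 61 (28 higher and 33 lower) and limma voom with library weights 0. The unadjusted count was 1069 without high replicate 1 and 4083 without high replicate 2.

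The doses were also compared with each other, to ask whether any gene depends on which dose was given. The smallest p-values belonged to Tsr1, at 4.06 ± 0.76 CPM in low, 1.68 ± 0.21 in medium and 4.10 ± 0.77 in high, to Abcb6, at 19.5 ± 2.79, 14.1 ± 4.74 and 7.45 ± 1.33, and to the insulin-repressed gene Igfbp1, at 5.70 ± 1.98, 2.66 ± 0.77 and 14.1 ± 8.04 (SD, n = 3 each). Fam160a2 and Rhob followed, and all 5 had adjusted p = 0.986. edgeR's quasi-likelihood test called 0 genes, with 614 at an unadjusted p under 0.05 where chance gives 842, and DESeq2 called 16 and limma voom with library weights 12. The edgeR count was 2 without low replicate 3 and 4 without high replicate 2, where 1270 and 2420 genes reached an unadjusted p under 0.05. Between doses, 22 lists separated high from low with the preset correlation (20 higher and 2 lower), 17 separated high from medium and 9 medium from low, and none did with an estimated correlation (smallest adjusted p = 0.322, 0.214 and 0.999). Fold changes against the shared controls correlated across 9641 genes at r = 0.623 between low and medium, 0.718 between low and high and 0.649 between medium and high, where simulated unchanged groups gave 0.503, 0.499 and 0.504. The covariances were 0.118, 0.186 and 0.166 against 0.0942, 0.0933 and 0.0943 in the simulation. The simulated groups also shared their controls, but simulated genes varied independently. Whether the excess comes from the 3 real controls, where genes vary together, from uneven mitochondrial shares, or from curcumin cannot be told apart here. Genes are not independent replicates in these correlations.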

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

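The alternatives with the mitochondrial share and without its genes, and all those of the 9 curcumin libraries against control, were chosen after the data were seen. Counts of genes stayed at 0 for low, medium, high, the slope and among doses with DESeq2 size factors, without a filter, with the stricter filter, with a fold threshold, with the mitochondrial covariate and without mitochondrial genes and copies. Replicate numbers gave no clear pairing: correlations of same-numbered libraries ran from -0.257 to 0.445, and 6 of 12 libraries lay closest to their own number. The mean correlations were 0.0372, 0.0586 and -0.0624 for replicates 1, 2 and 3, against -0.00616 for other numbers. No test of this was run, so a pairing cannot be excluded. With the replicate block 0 genes were called in each of these comparisons and 18, 22 and 27 lists at low, medium and high. DESeq2 called 32, 80, 157, 61 and 16 genes for low, medium, high, slope and among doses, of which 9, 13 and 16 of the dose calls had a group at 0 counts throughout. limma voom with library weights called 35 at medium, 256 at high and 12 among doses, and fits with only the groups compared called 1 at low and 8 at medium. The causes of these moves were not tested. Leaving out 1 library at a time gave 0 to 2 genes for low, 0 to 4 among doses, 14 to 26 lists for low and 14 to 27 for medium. The counts of 22, 22 and 25 lists became 0, 1 and 0 with an estimated correlation and 5, 1 and 0 by fry, which use the co-variation of genes between libraries. As fry does not set a list against the other genes, its counts answer another question than those of camera. The 9 curcumin libraries against control gave 1 gene, 0 to 9 with 1 library left out, 140 by DESeq2, 17 by limma voom, and 0 with the stricter filter, the replicate block or the mitochondrial covariate.

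Slamf8 kept its negative sign at each dose: with 1 library left out it ran from -1.56 to -1.03 at low, -3.06 to -1.74 at medium and -1.29 to -0.68 at high. It was too low for the stricter filter, which gave no value. Rela at low, near 0, turned to 0.0127 with limma voom and ran from -0.174 to 0.0543 with 1 library left out. Rela at high turned to 0.16 with the mitochondrial covariate, and Nfkbia at medium ran from -0.193 to 0.0607 with 1 library left out. Lists that move with the mitochondrial share also turned. With the share as a covariate this held for ribosomal proteins at medium (adjusted p = 0.286) and for activated stellate (0.417), hepatocyte (0.531) and oxidative phosphorylation (0.36) at high. Ribosomal proteins at medium turned without medium replicate 1 (0.113), where adjusted p ran from 3.07e-07 to 0.432 with 1 library left out. Depth limits genes such as Slamf8 and Tnf, with 0 to 54 and 3 to 97 raw counts per library.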

Other observations

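The tests of the 9 curcumin libraries as 1 group, of hepatocyte share, of nuclear RNA, of dose and its trend against the mitochondrial share, and of heat shock, clock and feeding genes were chosen only after the result was seen. The thresholds for the dose and clock tests were also changed after their values were known. Of the lists not yet described, erythroid genes lay lower in all 8 members at the high dose (median log2 fold change -2.22, adjusted p = 0.0064; adjusted p = 0.601 with an estimated correlation). This rests on control replicates 1 and 2, with scores of 1.24 and 2.22, while control replicate 3, at -1.27, lay below all 3 high libraries (exact permutation p = 0.4). The score difference of -1.54 became -0.799 without control replicate 2 and -2.54 without control replicate 3. Heat shock genes lay higher in 11 of 13 members there (median 0.66, adjusted p = 0.00286; adjusted p = 0.601 with an estimated correlation), and the chaperone gene Hsph1 stood at 1.46 ± 0.48, 1.58 ± 0.48 and 1.69 ± 0.48 (SE) from low to high, the last being 0.96 without high replicate 2. The heat shock list moved against the mitochondrial share by Pearson's r (-0.677, adjusted p = 0.031 by permutation). By Spearman's rho it did not pass (-0.364, adjusted p = 0.348 by permutation). Its score difference at the high dose went from 0.548 to 0.353 without high replicate 1. Cell cycle genes lay lower in 24 of 33 members at the low dose (adjusted p = 0.0033; adjusted p = 0.305 with an estimated correlation), with a score difference that went from -0.571 to -0.332 without control replicate 2. Among cytochrome P450 genes at the low dose, Cyp3a44, a form expressed mainly in females, was at -2.99 ± 0.71 (adjusted p = 0.764), and the list gave no call (adjusted p = 0.659). The clock gene Nr1d1 was at -1.07 ± 0.33 at the low dose, and Per1 was at 1.11 ± 0.32 at the medium and 1.02 ± 0.32 at the high dose. Osgin1, an NRF2 target, was at -1.98 ± 0.47 at the high dose (-1.26 without control replicate 3), where the NRF2 list as a whole gave no call (adjusted p = 0.54). At the medium dose 20 of 30 NRF2 genes lay lower, with a median of -0.15. The camera adjusted p there was 0.0176 with the preset correlation and 0.694 with an estimated correlation. Scaled by library totals, that median turned to 0.228.

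Taking the 9 curcumin libraries together against the 3 controls, edgeR called 1 gene of 16839, an ID without a symbol that was higher (adjusted p = 0.0376), with 1627 at an unadjusted p under 0.05, while DESeq2 called 140 and limma voom with library weights 17. The genes next in rank were Tnfaip2 (log2 fold change -1.56 ± 0.24, adjusted p = 0.0702), Junb (-1.57 ± 0.27, adjusted p = 0.095) and Tcim (2.36 ± 0.43, adjusted p = 0.16). Without control replicate 1, control replicate 3 or high replicate 2 the count of 1 became 9, 5 or 3, and it became 0 without low replicate 2 or 3, any 1 of the medium libraries, or high replicate 1 or 3. As many genes came from 3 of 30 splits of the 12 libraries into 9 and 3 (highest other 1), so chance cannot be excluded for this count.

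Other splits of the libraries bear on the counts of genes and lists. Where the real count of genes is 0, every split gives as many (10 of 10 at each dose, 30 of 30 for the slope and among doses), so these counts say nothing about chance. The highest other was 1 at low, 4 at medium, 1 at high, 1279 for the slope and 11 among doses. The 1279 genes of a single split point to a structure among the libraries other than dose order. For lists, 10 splits of 6 libraries are too few for a share under 0.05: 3 of the 10 splits gave as many as the real 22 at low (highest other 24), 2 gave as many as the real 22 at medium (highest other 25) and 2 as many as the real 25 at high (highest other 26).

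The mitochondrial share of the counts, with the hepatocyte, ribosomal protein and oxidative phosphorylation lists moving against it, separates the libraries most. A smaller share of hepatocytes alone would raise the markers of all other cell types in the high-share libraries. The sinusoidal endothelium list instead moved by -0.326 ± 0.0699 log2 units per 10 percentage points, against hepatocyte share as the only cause. It had the lowest slope of the lists used for this test. The Kupffer cell and T and NK cell lists, at -0.0599 ± 0.111 and -0.0466 ± 0.125, moved clearly in neither direction. A smaller hepatocyte share beside other changes is therefore not excluded. Dose stays open: the groups held 28.1% of the variance of the share (95% upper bound 50.2%), close to the 27.3% of permuted groups (permutation p = 0.425), and its slope on dose was -15.3 ± 7.79 points over 100 mg/kg (permutation p = 0.0751). Both values depend on high replicates 1, 2 and 3, which lay far apart at 30.3%, 64.7% and 42.1%. More nuclear and less cytoplasmic RNA in libraries with a high mitochondrial share may play a part. On this share, 13 nuclear-retained RNAs had a median slope 0.267 above that of protein-coding genes. Their slopes ran from -0.0681 ± 0.178 (Rian) to 0.623 ± 0.0721 (Kcnq1ot1). Neat1, Xist and Malat1 were at 0.518, 0.442 and 0.225, and Airn, Ftx and Pvt1 at 0.113 ± 0.159, 0.0742 ± 0.138 and 0.0508 ± 0.174. A share of 0.0151 of random protein-coding sets of that size differed as much. That share treats the RNAs as independent and does not measure the spread between libraries. Nor does it show why the mitochondrial counts themselves rise. Transcript length stays open, with a Spearman rho of 0.178 between slope and length across protein-coding genes.

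Immediate early genes and TNF and NF-κB genes scored lower in curcumin livers, by -0.951 ± 0.276 and -0.508 ± 0.11 in list score over 9 libraries against 3 (exact permutation p = 0.00909 and 0.00455, the latter the smallest possible and neither adjusted over the 48 lists; camera adjusted p = 0.25 and 0.163 with an estimated correlation). Without control replicate 2 the TNF and NF-κB difference was -0.333. The immediate early means were 0.713 in control, -0.481 in low, -0.519 in medium and 0.287 in high. At the high dose these scores overlapped the controls (exact permutation p = 0.2), with high replicate 1 at 0.629 above control replicate 1 at 0.475. With the mitochondrial share as a covariate the immediate early difference was -1.14 ± 0.255 and the TNF and NF-κB difference -0.504 ± 0.125. The share therefore does not account for these differences. Fewer immune cells may account for part of them. With the mean score of the Kupffer, neutrophil, T and NK, and B cell lists as a covariate they shrank to -0.708 ± 0.333 and -0.318 ± 0.0969. Handling at dissection cannot be told apart from curcumin, because cage and order of dissection may follow the groups, and the heat shock list, at 0.333 ± 0.239 (0.154 ± 0.21 with the mitochondrial share as a covariate, and 0.514 and 0.213 without control replicates 2 and 3), does not decide it.

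Gluconeogenesis and insulin response genes scored higher in curcumin livers, by 0.38 ± 0.145 (exact permutation p = 0.0364, not adjusted over the 48 lists; camera adjusted p = 0.287 with an estimated correlation). This rests on control replicates 2 and 3, since control replicate 1 scored above 7 of the 9 curcumin libraries, and the difference was 0.586 without control replicate 1 and 0.25 without control replicate 2. The hour of dissection stays open: 9 evening clock genes lay 0.61 ± 0.256 above 5 morning clock genes in curcumin against control livers (exact permutation p = 0.0273; 0.318 without control replicate 1 and 0.928 without control replicate 3), but across the 12 libraries the list score did not rise with this clock difference (r = -0.0536, permutation p = 0.875; Spearman rho = -0.133, permutation p = 0.682). Fasting stays open, with genes raised by fasting lying 0.553 ± 0.499 above genes raised by feeding (exact permutation p = 0.314). So does the mitochondrial share, with a difference of 0.317 ± 0.152 once it is a covariate. An effect of curcumin on glucose metabolism cannot be told apart from these here.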
